A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

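Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in budding yeast that carried a tandem affinity purification (TAP) tag on 1 of 3 proteins. Rvb1 and Rvb2 are related AAA+ ATPases found together in several chromatin remodelling complexes. Pgk1, a glycolytic enzyme, served as the control pulldown. Per the labels, the cells were of the W303 strain, were grown at 30 degrees to log phase and were starved of glucose for 10 min, and the tagged proteins were isolated from sonicated lysates with rabbit IgG. Libraries were read on a NextSeq 500 in single-end mode over 75 cycles. There were 9 libraries, with 2 pulldowns and 1 input for each tagged strain. The labels do not say that the 2 pulldowns of a strain came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

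The deposited values are raw read counts per gene, in 1 table for promoter windows of 500 bp and 1 table for gene body windows of 500 bp, with 7036 windows in each. FastQC, Bowtie2, SAMtools, Picard, deepTools and bedtools were used, per the submitters' processing notes, which give no order or role. The genome build, the exact placement of the windows and the treatment of duplicate reads are not given in the sources used here. Counts in every library reached a maximum of 1148 to 1151. The number of distinct single-end reads of 75 bases that can touch a window of 500 bp is 1148 over both strands, so the counts have the ceiling that removal of duplicate reads would give. The median promoter window stood at 53.6% to 57.1% of that ceiling in the inputs and at 8.62% to 30.1% in the pulldowns, so differences are compressed, most of all in the inputs. Intervals cover counting error only, and p-values cover counting error and the spread between libraries only.

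Of the 7036 window identifiers, 6078 were matched to a gene of the R64 reference table and are printed with its symbol; the others keep the identifier of the files. How reads that map to several places were treated is not given in the sources used here either, so values of near-identical copies (ribosomal protein gene pairs, seripauperin genes, ribosomal DNA) are uncertain. Because no build is named for the files, no coordinates are given, and the table was used only for names and for which genes neighbour each other. Where 2 genes are divergent neighbours, their promoter windows can cover the same sequence.

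Counts were tested with edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) after filterByExpr and TMM normalisation within each table, in 1 fit of the 9 libraries with 4 groups (Rvb1 IP, Rvb2 IP, Pgk1 IP and Input), which leaves 5 residual degrees of freedom. A window was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 values are fold changes with a standard error (SE) derived from the test's p-value. The promoter and gene body counts of the same gene were joined in a further fit with the library as a block and 1 library size for both windows, and the interaction of window and group was tested. The 13 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM (counts scaled to the library total, prior count 2), with fry and with camera at an estimated correlation beside it. The difference between the storage carbohydrate and chaperone lists was tested by permuting list labels over genes with 100000 resamples.

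The named genes were chosen by a rule fixed before the data were examined. For the promoter comparisons of Rvb1 and Rvb2 with Pgk1 the rule takes the 8 largest positive and 4 largest negative log2 fold changes among called windows with a mean count of at least 20 and both pulldowns on the same side of the control libraries, and for the other comparisons 3 and 2. It adds GSY1, GLC3, GPH1, HXK1, HSP30, HSP26, HSP12, HSP104, PGK1, RVB1 and RVB2, and the 2 members of each list with the smallest p. Not all of the genes it takes are printed.

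Alternatives were other size factors, library totals, filters on low counts, DESeq2 (1.42.0), a fold threshold of 1.5, each pulldown relative to its own input, the pulldowns alone, the replicate number as a block, windows without divergent neighbours, and leaving out each library in turn. A correction for the position ceiling, windows matched to the reference table, windows with like input counts, the Rvb inputs averaged as 1 library, a robust estimate of the spread, the 2 Pgk1 libraries split between the Rvb proteins, and list tests without each library in turn were added after seeing the data. A correction for GC content was not run, since it needs the sequence of each window.

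The inputs of the Rvb1 and Rvb2 strains differed by less than Poisson noise at promoters (chi-square per degree of freedom 0.608) but by more than the 0.460 that counting with this ceiling gives, so both were kept as separate libraries, with their average as an alternative. The Pgk1 input gave 1.67 and 1.71 with the Rvb1 and Rvb2 inputs. The pulldown pairs gave 5.61 for Rvb1, 4.15 for Rvb2 and 6.16 for Pgk1. The fit of the 9 libraries takes 1 spread from inputs and pulldowns together. The SE and p-values of a pulldown against a pulldown may therefore be too small.

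The fits were tested on simulated counts with 200 windows changed. For promoter windows of Rvb1 against Pgk1, over 7034 windows, the share recovered was 55.2% at 1.5-fold, 94.0% at 2-fold and 100% at 4-fold, and 5.14% of calls were unchanged windows. The simulation has no ceiling and uses the average spread of all libraries. For the interaction fit of Rvb1 over 7034 windows, 5.56% of calls were unchanged windows when both windows of a library were given the same total. With the real window totals this was 40.8%, since the fit then counts a promoter excess over the whole genome as a change of each window.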

Results

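The data are read counts in the promoter and gene body windows of 7036 yeast genes, from cells starved of glucose for 10 min. The comparisons ask where on the genome the ATPases Rvb1 and Rvb2 were recovered beyond a control protein, Pgk1, and beyond the chromatin before pulldown. Each pulldown group held 2 libraries and the input group held 3. The total count at promoters was 1993420 and 1278825 for Rvb1, 1217928 and 1625081 for Rvb2, 806134 and 2516799 for Pgk1, and 4342277, 4407851 and 4636420 for the inputs. At gene bodies the totals ran from 782398 in Pgk1 replicate 1 to 4701031 in the input of the Pgk1 strain.

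Promoter windows held a larger share of the reads in each of the 4 Rvb pulldowns than in any of the Pgk1 pulldowns and inputs. Reads in promoter windows were 54.3% ± 2.42 (SD, n = 2) of the reads in both windows for Rvb1, 52.7% ± 1.81 (SD, n = 2) for Rvb2, 50.3% ± 0.645 (SD, n = 2) for Pgk1 and 49.6% ± 0.117 (SD, n = 3) for the inputs. The lowest Rvb library, Rvb2 replicate 2, stood at 51.5% (95% Wilson interval 51.4% to 51.5%) and the highest control library, Pgk1 replicate 1, at 50.7% (50.7% to 50.8%). These intervals cover the counting error within 1 library and not the spread between libraries, so they do not show that the groups differ. Over the 4 Rvb pulldowns the mean was 53.5%, which was 3.89 percentage points above that of the inputs. An exact two-sided permutation test of these 4 pulldowns against the 3 inputs gave p = 0.0571, since 2 of the 35 arrangements differed by as much. No arrangement had a larger difference in the observed direction, so with these values 0.0571 is the smallest p that a higher Rvb share could reach. With 2 libraries against 2, the exact test of either Rvb protein against Pgk1 cannot go below 0.333.

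**Figure D1:**
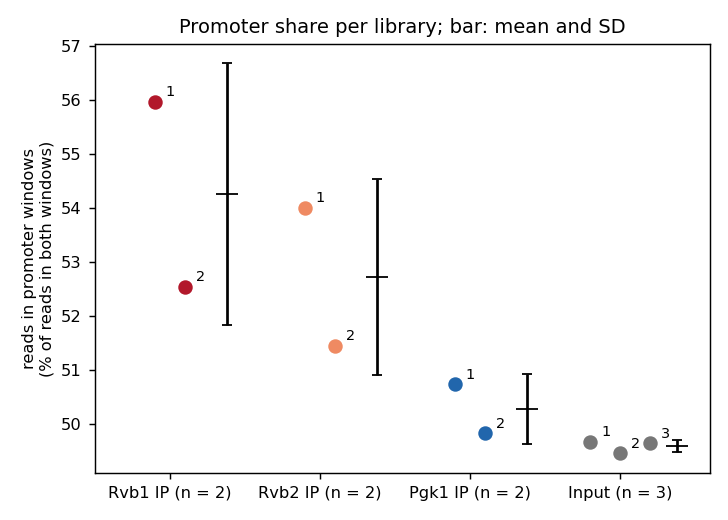
Share of reads in promoter windows, as a percent of the reads in promoter and gene body windows (y axis, not starting at 0), for each library of the 4 groups (x axis). Points are libraries with their replicate number, and bars are the group mean and SD. The 4 Rvb pulldowns lie between 51.5% and 56.0%, above the Pgk1 pulldowns and the inputs, which lie between 49.5% and 50.7%.

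At promoters, the window shared by RQC1 and SWR1 was among the windows highest in Rvb1 over Pgk1. SWR1 encodes the ATPase of the SWR1 chromatin remodelling complex, of which Rvb1 and Rvb2 are subunits, and RQC1 is its divergent neighbour. The log2 fold change was 1.76 (SE 0.32, edgeR quasi-likelihood test, adjusted p = 0.0130), with 409 ± 36.7 CPM (SD, n = 2) in Rvb1, 385 ± 185 (SD, n = 2) in Rvb2, 121 ± 3.63 (SD, n = 2) in Pgk1 and 130 ± 6.57 (SD, n = 3) in the inputs. MRPL8, a mitochondrial ribosomal protein gene, rose by 1.25 (SE 0.25), QRI5 by 1.26 (SE 0.27) and MGM1, a gene of mitochondrial fusion, by 1.23 (SE 0.26). SLK19 and YPR170W-A rose by 1.23 and 1.24. TIM9, which neighbours URA3, stood at 1.43 (SE 0.45, adjusted p = 0.0360), but at -0.32 when each pulldown was set against its own input. The 4 lowest of the called windows, YMR326C, YNR077C, YAR075W and YMR324C, lay at -3.11 to -2.16. They were also low in the inputs of the Rvb strains, YMR326C having 82 and 96 counts there and 679 in the input of the Pgk1 strain.

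Of 7034 promoter windows, 1708 differed between Rvb1 and Pgk1, 866 higher and 842 lower in Rvb1 (edgeR, adjusted p under 0.05). The split depended on the scaling: with the total over both windows as library size it was 1318 higher and 584 lower, and the median over all windows moved from -0.05 to 0.05. With the replicate number as a block, a fit of the pulldowns without the inputs called 1517, 659 higher and 858 lower, though the labels do not pair the pulldowns. Without that block the count rested on single libraries and on the inputs. It was 0 without Rvb1 replicate 1 (1171 at an unadjusted p under 0.05), 3157 without Rvb1 replicate 2, 723 without Pgk1 replicate 2 (207 higher and 516 lower), 797 without input 1, 755 without input 2, 971 without input 3 and 438 with the pulldowns alone (146 higher and 292 lower). Relative to each strain's own input no window was called by edgeR, with 395 at an unadjusted p under 0.05; the median size of the 1708 fold changes was 0.59 before and 0.57 after, while the median SE went from 0.16 to 0.34. That like size is no separate support, since both contrasts use the same pulldowns and the 1708 windows were selected in them. At 2 libraries against 2, 1995 windows had both Rvb1 pulldowns above both Pgk1 pulldowns and 1981 had them below, together 56.5% of windows. The share was 42.5% for Rvb2 against Pgk1 and 23.3% for Rvb1 against Rvb2. Exchangeable libraries give 33.3% per window. Windows of a library vary together, so no conclusion about chance is drawn from these shares.

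For Rvb2 against Pgk1 no promoter window was called by edgeR, with 1227 at an unadjusted p under 0.05, and DESeq2 called 143, of which 107 were higher. The edgeR calls of the alternatives were mostly lower: without Pgk1 replicate 2 there were 3 higher and 105 lower, without input 3 there were 4 and 23, and with the pulldowns alone 4 and 19, while both calls without Rvb2 replicate 2 were higher. At the RQC1 and SWR1 window Rvb2 replicate 2 was the lower of its pair, with 408 counts against 607 in replicate 1. Set against each other, Rvb1 and Rvb2 differed at no promoter window by edgeR, with 416 at an unadjusted p under 0.05 and 1 by DESeq2, and at no gene body window by edgeR or DESeq2, with 518 and 480 at an unadjusted p under 0.05. The calls for Rvb1 and their absence for Rvb2 therefore do not show that the proteins differ; without Rvb1 replicate 2 the same test called 194 promoter and 245 gene body windows. Over promoter windows, which are not independent, the 2 sets of fold changes against Pgk1 had a Pearson correlation of 0.918 and a covariance of 0.134. Unchanged groups simulated with shared controls gave 0.497 and 0.0163, a covariance difference of 0.117. All simulated libraries, the controls included, were drawn with the average spread of all libraries. The real Pgk1 pulldowns differed by more than the Rvb inputs did (chi-square per degree of freedom 6.16 against 0.608). The simulated covariance may therefore be too small for the real Pgk1 controls, and no conclusion is drawn from that difference. With 1 Pgk1 library as the control of Rvb1 and the other as that of Rvb2, the correlation was 0.583 and, the other way round, 0.525, with covariances of 0.103 and 0.0963. No Pgk1 library was then shared, and the covariances were below 0.134, so part of that value may come from the shared controls. Both Pgk1 libraries are of 1 strain, so any effect of that strain stays on both sides. With Rvb2 set against the inputs, so that no library was shared, the correlation was 0.666, and with Rvb2 set against its own input, where none was shared either, it was 0.460.

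Among genes of storage carbohydrate metabolism, 3 of 22 promoters rose and 1 fell in Rvb1 over Pgk1. Over all promoter windows 24.3% were called in this comparison, so the called members alone do not set this list or the chaperones apart. Adjusted over the list alone, edgeR called 0, with 6 at an unadjusted p under 0.05, and DESeq2 over all windows called 3. GLG1, a glycogenin gene, rose by 0.36 (SE 0.11, adjusted p = 0.0333) and PIG2, a regulator of glycogen synthase, by 0.39 (SE 0.13, adjusted p = 0.0413). The glycogen genes GSY1, GLC3 and GPH1 had log2 values of 0.47, 0.51 and 0.43 in Rvb1 and 0.36, 0.50 and 0.31 in Rvb2, none past the test. Among 26 chaperone genes 2 rose and 2 fell in Rvb1, the same numbers when adjusted over the list alone. SSA3 fell by 0.79 (SE 0.21) and HSC82 fell by 0.55 (SE 0.16), whereas HSP30, HSP12, HSP104 and HSP26 stood at 0.41, 0.26, 0.26 and -0.02 and did not pass. For Rvb2 edgeR and DESeq2 called 0 members of either list, with 5 storage and 2 chaperone promoters at an unadjusted p under 0.05 in edgeR. The Pgk1 library used set the sign of GPH1 and HXK1: without Pgk1 replicate 2 GPH1 in Rvb2 was -0.11, and without Pgk1 replicate 1 HXK1 was 0.37 in Rvb1 and 0.30 in Rvb2.

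The mean of the storage list exceeded that of the chaperone list by 0.15 in Rvb2 (permutation test over genes, p = 0.0207, adjusted over both comparisons 0.0414) and by 0.14 in Rvb1 (permutation p = 0.0834, adjusted 0.0834). The means were 0.17 and 0.02 in Rvb2, and 0.21 and 0.07 in Rvb1, over 22 and 26 genes, which are not independent replicates. The size followed the control library used: without Pgk1 replicate 2 the differences were 0.03 in Rvb2 (permutation p = 0.618) and 0.02 in Rvb1, and without Pgk1 replicate 1 they were 0.30 and 0.29 (permutation p = 0.00861 in Rvb1). With counts corrected for the position ceiling, an alternative chosen after seeing the data, the Rvb1 difference was 0.19 (unadjusted permutation p = 0.0478). Without Rvb2 replicate 1 the Rvb2 difference was 0.07 (permutation p = 0.180). At gene bodies it had the opposite sign, at -0.15 in Rvb1 (permutation p = 0.0298) and -0.16 in Rvb2, where the permutation p was smaller.

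The promoters of the storage, glycolysis, respiration and histone lists stood above the other windows in Rvb1 over Pgk1, and those of the ribosomal protein, ribosome biogenesis and meiosis lists below them (camera, preset correlation). The adjusted p was 0.0311, 0.0168, 0.0127 and 0.0176 for the first 4, and 3.12e-06, 0.0179 and 0.00225 for the others. Each of these 7 had adjusted p = 0.722 with an estimated correlation in Rvb1. The same 7 lists passed for Rvb2, with adjusted p = 0.840 with an estimated correlation for each. No list had an unadjusted p under 0.05 with an estimated correlation. The fry test asks another question, whether a list differed from no change, and its smallest adjusted p was 0.252 in Rvb1 and 0.611 in Rvb2. Each of the 7 lost its call without at least 1 library. Without Pgk1 replicate 2 the ribosomal protein list passed in Rvb1 and in Rvb2 and the other 6 did not, the mean of the storage list in Rvb1 going from 0.21 to -0.0018 and that of glycolysis from 0.27 to -0.01. Without Pgk1 replicate 1 the ribosomal protein list did not pass, its mean going from -0.18 to -0.03 in Rvb1 (camera adjusted p = 0.162) and from -0.14 to 0.0042 in Rvb2, where camera still ranked it lower (adjusted p = 0.687). Without Rvb1 replicate 1 the ribosomal protein and meiosis lists passed in Rvb1, and without Rvb2 replicate 1 the ribosomal protein list passed in Rvb2.

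Within those lists, called members alone are no evidence of a list difference, since 24.3% of all promoter windows were called, 866 higher and 842 lower. Of 19 glycolysis promoters 2 rose, PDC1, the main pyruvate decarboxylase gene, by 0.84 (SE 0.27), and PFK2 by 0.47 (SE 0.15). Adjusted over the list alone, edgeR called 0 of them, with 4 at an unadjusted p under 0.05, and DESeq2 called 2. Of 38 respiration promoters 6 rose and 1 fell, and 2 rose when adjusted over the list alone; COX5A, a cytochrome c oxidase gene, rose by 0.63 (SE 0.17). Of the 10 histone promoters edgeR and DESeq2 called 0, also when adjusted over the list alone, with 2 at an unadjusted p under 0.05 in edgeR; HTZ1, the H2A.Z gene, stood at 0.52 and HTB1 at 0.50. Of 137 ribosomal protein promoters 16 fell and 3 rose, and 11 and 2 when adjusted over the list alone; RPS8B fell by 0.75 (SE 0.16). Of 35 ribosome biogenesis promoters 3 fell and 1 rose, also when adjusted over the list alone, and NOG2 fell by 0.94 (SE 0.22). Of 21 meiosis promoters 4 fell, also when adjusted over the list alone, and DMC1, the meiotic recombinase gene, fell by 1.02 (SE 0.24).

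In the lists that did not pass as a set, 4 of 22 general stress promoters rose, MSC1 by 0.81 (SE 0.24), and 1 of 11 promoters of glucose-repressed uptake rose, SUC2, the invertase gene, by 0.41 (SE 0.11). HXK1 stood at -0.14 in Rvb1. The adjusted p of camera was 0.0507 for general stress, 0.427 for chaperones, 0.433 for glucose-repressed uptake, 0.843 for alternative carbon and for phosphate and inositol, and 0.123 for galactose. General stress passed without Rvb1 replicate 2, Pgk1 replicate 1 or any 1 input, with an adjusted p of 2.53e-04 to 0.0478, and glucose-repressed uptake passed without Pgk1 replicate 1, with 8.18e-04. Of 23 alternative carbon promoters 1 rose and 3 fell, SFC1 and FDH1 among the latter. Of 15 phosphate and inositol promoters 1 rose and 2 fell, PHO8 by 0.60 (SE 0.16) upward, and PHO84 fell by 0.35. Of 7 galactose promoters 1 fell, GAL3, by 0.66 (SE 0.16). The phosphate and inositol list had a median of -0.09 and a mean just above 0. Adjusted over the list alone, these counts were the same except that 3 phosphate and inositol promoters fell. Here too the share to set them against is the 24.3% called over all promoter windows. The genes of the tagged proteins, PGK1, RVB1 and RVB2, stood at 0.18, 0.13 and 0.24 at their promoters in Rvb1 and did not pass.

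**Figure D2:**
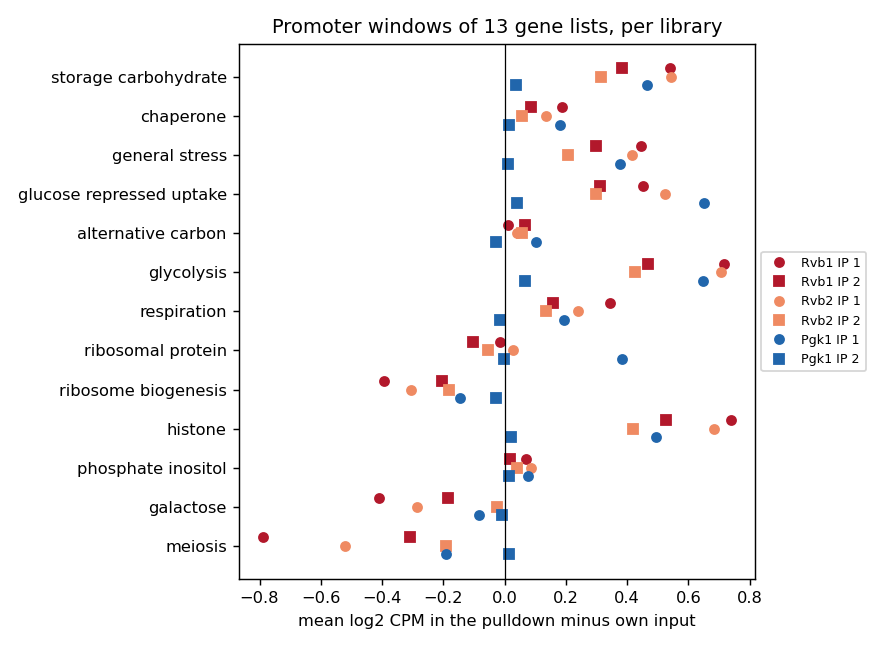
Mean log2 CPM of the pulldown minus the input of the same strain (x axis) over the promoter windows of each of the 13 gene lists (y axis), 1 point per pulldown library; circles are replicate 1 and squares replicate 2. The glycolysis list stands at 0.72 and 0.47 in Rvb1, 0.71 and 0.43 in Rvb2, and 0.65 and 0.07 in Pgk1, so that Pgk1 replicate 1 lies near the Rvb pulldowns and Pgk1 replicate 2 near the input.

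Against the inputs, 3642 promoter windows differed in Rvb1, 1784 higher and 1858 lower. Without Rvb1 replicate 1 edgeR called 0, with 1969 at an unadjusted p under 0.05, and without input 1, 2 or 3 it called 2020, 2077 and 2152. Against the strain's own input alone it called 5 higher and 50 lower. The RQC1 and SWR1 window was higher by 1.66 (SE 0.28, edgeR adjusted p = 0.00438), and YKR104W and YOL160W fell by 1.46 and 1.35. For Rvb2 no window was called by edgeR, with 2676 at an unadjusted p under 0.05 and 1499 called by DESeq2; edgeR called 2132 and 1973 without Rvb1 replicate 1 or 2, which enter the shared spread, 1376 and 1272 without Pgk1 replicate 1 or 2, and 1308 without Rvb2 replicate 2. For Pgk1 no window was called by edgeR, with 677 at an unadjusted p under 0.05, and DESeq2 called 199, all higher; edgeR called 867 without Pgk1 replicate 2 and 43 without input 3. The storage list lay above own input by 0.47 in Pgk1 replicate 1 and by 0.04 in replicate 2, beside 0.54 and 0.38 in Rvb1.

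At gene bodies, MET17 and URA3 had the largest values higher in Rvb1 than in Pgk1, at 3.80 and 3.59, and PRM7 fell by 2.32. URA3 had 8 counts in the input of the Pgk1 strain against 615 and 687 in those of the Rvb strains, and MET17 had 7 against 650 and 702. Both had the opposite sign when each pulldown was set against its own input, at -2.75 and -2.80. In all, 969 of 7035 gene body windows differed between Rvb1 and Pgk1, 471 higher and 498 lower. With the total over both windows as library size the split was 285 higher and 511 lower, and that scaling moved the median over all windows from -0.05 to -0.21. DESeq2 called 1314. By edgeR the count was 0 without Rvb1 replicate 1 (790 at an unadjusted p under 0.05), 2959 without Rvb1 replicate 2, 1477 and 1464 without Rvb2 replicate 1 or 2, 15 without Pgk1 replicate 2, and 51, 89 and 292 without input 1, 2 or 3. Against own input it was 1, and with the pulldowns alone 128. For Rvb2 no gene body window was called by edgeR or DESeq2, with 760 and 753 at an unadjusted p under 0.05; edgeR called 30 without input 3 (5 higher and 25 lower), 29 with the pulldowns alone (6 and 23), and, all lower, 3 without Pgk1 replicate 2 and 1 against own input. With the replicate number as a block, edgeR called more gene body windows for Rvb2 than in any of these alternatives, as given below. At gene bodies 4 lists passed in Rvb1 and 3 in Rvb2, all lower by camera. Ribosome biogenesis in Rvb1 had 6 of 35 windows lower, and 18 when adjusted over the list alone; its adjusted p was 3.50e-06, and adjusted p = 0.806 with an estimated correlation. The other lists were ribosomal protein, meiosis and, in Rvb1, galactose, with 13, 8 and 2 windows lower in Rvb1, 13, 11 and 3 when adjusted over the list alone, and adjusted p = 0.806 with an estimated correlation for each. In Rvb2 the ribosomal protein list had adjusted p = 0.770 with an estimated correlation, and ribosome biogenesis and meiosis had adjusted p = 0.926 with an estimated correlation. Without Pgk1 replicate 1 the lists past the test were 8 in Rvb1 and 10 in Rvb2, and without Pgk1 replicate 2 they were 9 and 7, with a glycolysis mean in Rvb1 of 0.63 in the first case and -0.49 in the second. Galactose in Rvb1 did not pass without Rvb1 replicate 1 or Pgk1 replicate 1, nor did ribosome biogenesis and meiosis in Rvb2 without Rvb2 replicate 1 or Pgk1 replicate 2.

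**Figure D3:**
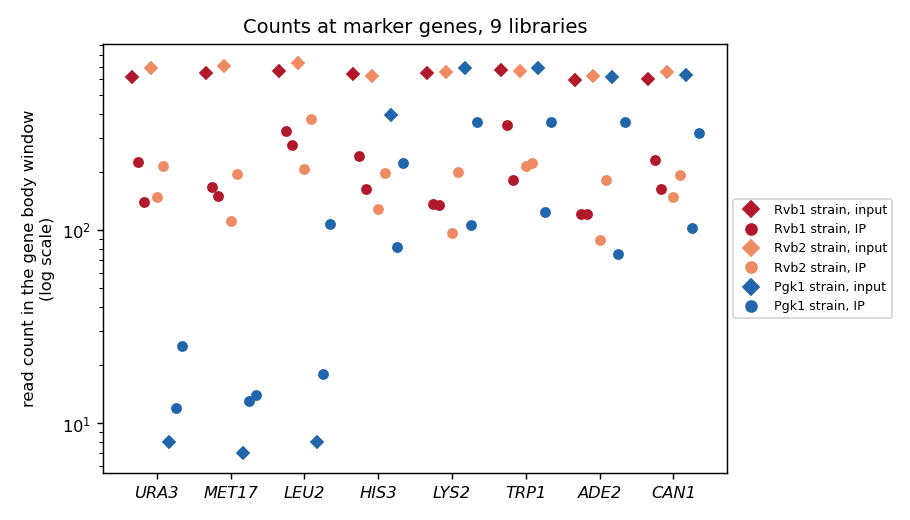
Read counts (y axis, log scale) in the gene body windows of 8 genes that serve as markers in laboratory yeast (x axis), for the 9 libraries; diamonds are inputs and circles pulldowns, coloured by tagged strain. At URA3 and MET17 the 3 libraries of the Pgk1 strain hold 7 to 25 counts, while LYS2 and TRP1 have like counts in the 3 inputs.

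The contrast of Rvb1 with Pgk1 was higher at the promoter than at the gene body of the same gene for 1729 genes and lower for 270, of 7035 tested (edgeR interaction test). RQC1, SLK19 and XRN1, a gene of mRNA decay, were the highest of the called genes, at 1.76 (SE 0.33), 1.60 (SE 0.31) and 1.55 (SE 0.30), and YDL096C and YGR270C-A fell by 1.32 and 1.29. The median over all genes was 0.28, so these calls contain the larger promoter share given above. With each column scaled separately, which removes that shift, 628 genes were higher and 672 lower. The count was 0 without Rvb1 replicate 1, input 1 or input 2, with 1240, 2586 and 2605 at an unadjusted p under 0.05; it was 3642 without Rvb1 replicate 2, 420 without input 3 and 49 without Pgk1 replicate 2. For Rvb2 the median was 0.15 and no gene was called by edgeR, with 1194 at an unadjusted p under 0.05; edgeR called 32, 7 and 1 without Pgk1 replicate 2, input 3 or Rvb2 replicate 2.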

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

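The tests of mislabelling, depth, like input counts, the position ceiling, the promoter bias of pulldowns and the strains' input chromatin were chosen after the results were seen; the test on URA3 was written before its value was seen, though after low counts at LEU2 and beside MET17 had been.

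A signal appeared in the inputs, which the pulldown comparisons use only as a background. Between the input of the Pgk1 strain and those of the Rvb strains, 31 promoter and 29 gene body windows differed at least 2-fold. Of these, 26 and 23 were higher in the Pgk1 strain and 5 and 6 lower, while 0 windows differed so between the 2 Rvb inputs. Low depth is argued against by a Pgk1 input total of 1.05 times the larger Rvb input. A single mislabelled library is argued against by the gene body windows of URA3 and MET17, which were under 20% of the median window in 3 of 3 Pgk1-strain libraries. Their share was larger in the Pgk1 pulldowns than in the Pgk1 input. URA3 stood at 12.6% and 7.20% of the median window against 1.21%, and MET17 at 13.7% and 4.03% against 1.06%. A candidate explanation for windows lower in the Pgk1-tagged strain is that it has the auxotrophic deletions of the BY4741 background, although all strains are labelled W303. The URA3 gene body stood at 1.23% of the Rvb inputs while LYS2 was like them. At gene bodies LEU2 had 8 counts in the Pgk1 input against 662 and 726 in the Rvb inputs, and HIS3 had 395 against 638 and 625. The Pgk1 pulldowns held 18 and 107 counts at LEU2, which were 18.9% and 30.8% of their median window, against 1.21% in the Pgk1 input. The source of these reads was not tested, which is a limit of every contrast with the Pgk1 pulldowns. Deletions in the Pgk1 strain would not make the windows that were higher there. Some of these promoter windows held almost no reads in the Rvb inputs: YAR047C had 1 and 2 counts there against 640 in the Pgk1 input, and YNR071C had 0 and 1 against 624. Others were only lower in the Rvb inputs, such as YGL260W with 254 and 266 against 722. The strains' input chromatin therefore differed in both directions, and the cause of the windows higher in the Pgk1 strain was not tested. Input counts were alike in the strains (within 0.5 log2) at 6984 of 7036 promoter windows, and 31 of the 1708 Rvb1 calls lay in the others. Copy number differences that move the input count by more than that are therefore unlikely to make most of the calls. A separate fit of the windows with like input counts made 1780 calls, 1644 of them in both fits. That fit is no separate support, since it left out so few of the called windows that the count could hardly fall. The ceiling compresses input counts, so smaller copy number differences are not excluded. Any other effect of strain background on the pulldown is confounded with the tagged protein.

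Gene body windows of 2 lists lay on opposite sides of their own input in the Rvb and Pgk1 pulldowns, a difference that was not tested as such. In the camera test of Rvb against Pgk1, alternative carbon did not pass (adjusted p = 0.185 for Rvb1 and 0.275 for Rvb2). Ribosomal protein passed at the preset correlation only. For the alternative carbon list the Rvb mean minus the Pgk1 mean was -0.163 for Rvb1 and -0.0936 for Rvb2, and for the ribosomal protein list -0.177 for Rvb1 and -0.158 for Rvb2. Without replicate 1 of the Rvb protein the alternative carbon values were -0.0665 and -0.0410, without its replicate 2 they were -0.259 and -0.146, and without Rvb2 replicate 1 the ribosomal protein value of Rvb2 was -0.0934.

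The promoter share was higher in the 4 Rvb pulldowns than in the 5 other libraries. The position ceiling is argued against by the corrected shares, in which the lowest Rvb library stayed 0.865 percentage points above the highest of the others. For a promoter bias of any pulldown, the higher Pgk1 ratio of promoter excess to spread was 36.9% of the lowest Rvb ratio. This argues against such a bias as the whole of the Rvb excess only if the bias grows with the spread. There were 2 Pgk1 pulldowns, and both stood above own input, by 1.09 and 0.181 percentage points. A difference between the strains in the chromatin before pulldown is argued against by the inputs, which differed by -2.12% of the Rvb excess. GC content, which differs between promoters and gene bodies, was not tested because the window sequences were not used here. A GC bias of the Rvb pulldowns, a promoter bias of any pulldown and recovery of Rvb1 and Rvb2 at promoters therefore stay open. So does an effect of strain background on the pulldown, which is confounded with the tagged protein.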

How the results depend on the processing

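The position-ceiling correction, matched windows, like-input windows, averaged Rvb inputs, robust spread, split Pgk1 controls and list tests without 1 library were chosen after seeing the data. Causes were not tested except where stated. Of 2211 results for named genes, 1910 kept direction and side of the threshold, 256 lost the call, 20 gained it and 25 changed sign. Many had no call to lose, among them all for Rvb2 against Pgk1, so the pooled count does not measure how stable the called genes are. The settings also differed. Without a filter on low counts 101 of 101 stayed the same, while with the pulldowns alone 73 of 91 did, 17 lost the call and 1 changed sign.

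Leaving out 1 library in turn, promoter calls ran from 0 to 3157 for Rvb1 against Pgk1, 0 to 108 for Rvb2 against Pgk1, 0 to 194 for Rvb1 against Rvb2, and against the inputs 0 to 4260 for Rvb1, 0 to 2132 for Rvb2 and 0 to 867 for Pgk1. Gene body calls ran from 0 to 2959, 0 to 30 and 0 to 245 in the same order of pulldowns, and interaction calls from 0 to 3642 for Rvb1 and 0 to 32 for Rvb2. The storage minus chaperone difference ran from 0.0233 to 0.289 in Rvb1 and from 0.0339 to 0.299 in Rvb2. Lists past the test ran from 1 to 8 for Rvb1 and for Rvb2 at promoters, and from 4 to 9 and 3 to 10 at gene bodies. A group left with 1 library was assumed to vary like the others.

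At 1.5-fold or more the Rvb1 counts were 868 against Pgk1, 1372 against the inputs and 482 at gene bodies, as a stricter threshold must lower them. DESeq2 called 143 promoters for Rvb2 against Pgk1, 1 for Rvb1 against Rvb2, 1499 for Rvb2 against the inputs and 199 for Pgk1. With library totals Rvb2 against the inputs gave 523, and with matched windows 316. Relative to own input, Rvb1 and Rvb2 against Pgk1 gave 0 promoter calls, and 1 gene body call each; with own input only, Rvb1 gave 55 and Pgk1 gave 1. The pulldowns alone gave 438 and 23 promoter and 128 and 29 gene body calls for Rvb1 and Rvb2. Without divergent neighbours, which leaves out 3062 windows, Rvb1 gave 810 against Pgk1, 1913 against the inputs and 894 in the interaction. With the Rvb inputs averaged, Rvb1 gave 734, 1987 and 35 (gene body). Scaling each column gave 1300 interaction calls. List tests at an estimated correlation gave 0 of 7, 7, 4 and 3.

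With the replicate block, Rvb2 against Pgk1 gave 37 promoter and 77 gene body calls, Rvb1 gave 1475 gene body calls, and the Rvb1 storage difference was 0.156 (permutation p = 0.0479). Same-numbered pulldowns deviated together (over promoter windows r = 0.727 for Rvb1 with Rvb2, 0.226 for Rvb1 with Pgk1 and 0.348 for Rvb2 with Pgk1). Chi-square per degree of freedom at promoters was 2.42 between Rvb1 and Rvb2 replicates 1 and 1.69 between replicates 2. It was 5.61 within Rvb1 and 4.15 within Rvb2. Rvb1 replicate 2 with Rvb2 replicate 1 gave 2.12, and Rvb1 replicate 1 with Rvb2 replicate 2 gave 10.8. With 2 numbers and no shared batch in the labels, a pairing cannot be settled. Any shared effect stays in the spread of the fit without a block. With the block, Rvb1 against Rvb2 gave 0 promoter calls. The Rvb1 storage difference was 0.189 with the ceiling correction (permutation p = 0.0478), past the threshold that the reported value missed, and -0.146 in Rvb1 and -0.156 in Rvb2 at gene bodies.

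HSP26 in Rvb1 was 0.0838 with library totals, 0.0833 without divergent neighbours, and ran from -0.057 to 0.025 without 1 library. RVB2 in Rvb2 was 0.0448 with library totals, 0.00689 with DESeq2, 0.0785 with own input, 0.0163 with pulldowns alone, 0.0134 with the block, 0.00463 with averaged inputs, and -0.11 to 0.13 without 1 library. Without 1 library HXK1 ran -0.59 to 0.37 in Rvb1 and -0.67 to 0.30 in Rvb2, PGK1 -0.22 to 0.63 and -0.19 to 0.65, and in Rvb2 GPH1 -0.11 to 0.81 and HSP104 -0.0060 to 0.33. With own input TIM9 was -0.32, MET17 -2.80, URA3 -2.75, tL(CAA)C -1.01 and PAU11 0.0831; the first 4 had low counts in the input of the Pgk1 strain, 202 for TIM9, 7 for MET17, 8 for URA3 and 80 for tL(CAA)C.

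A correction for GC content and an exclusion of overlapping gene body windows were not run. Depth limits most the Pgk1 pulldown with a median of 99 counts per promoter window.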

Other observations

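The tests in this part were all chosen after the data had been seen.

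Promoter windows of tRNA genes were lower in Rvb1 than in Pgk1, although with an estimated correlation the class did not pass. Of 274 such windows, 119 were lower and 0 higher in Rvb1 than in Pgk1, with a median log2 fold change of -0.47. The number lower was 0 without Rvb1 replicate 1, with 65 lower at an unadjusted p under 0.05 by edgeR, and 61 without Pgk1 replicate 1; the median was -0.26 without Pgk1 replicate 1 and -0.76 without Pgk1 replicate 2. Without Pgk1 replicate 1 some tRNA windows were also called higher in Rvb1. For Rvb2 the median was -0.28. The mean over own input was 0.65 and 0.15 in the Pgk1 pulldowns, -0.18 and 0.05 in Rvb1, and 0.06 and 0.18 in Rvb2. The camera test with a preset correlation gave an adjusted p of 4.58e-21 for Rvb1, and an unadjusted p = 0.221 with an estimated correlation. The seripauperin genes are a family of near-identical subtelomeric copies whose reads cannot be assigned with certainty. Some already differed between the inputs, PAU19 having 104 and 123 promoter counts in the Rvb inputs and 677 in the Pgk1 input. The mean over own input was -0.70 and -0.14 in Rvb1, and -0.025 and 0.066 in Pgk1. Of the 24 windows of the family, 15 were lower in Rvb1 than in Pgk1. By camera the adjusted p was 4.24e-06, and an unadjusted p = 0.257 with an estimated correlation for these windows. By edgeR 0 of them were lower without Rvb1 replicate 1 and without Pgk1 replicate 2, with 7 and 9 at an unadjusted p under 0.05.

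The 2 Pgk1 pulldowns differed: the glycolysis promoters stood above own input in replicate 1 and close to it in replicate 2. Counting noise is argued against by a mean 18.1 times its Poisson standard error in replicate 1. The position ceiling is argued against by the slope of replicate 2 on replicate 1, which was 0.182 after correction. Replicate 2 may hold mostly chromatin that was not pulled down, since its spread beyond counting error was 0.296 times that of replicate 1. A lower spread in replicate 2 was not particular to Pgk1. This SD of log2 over own input was 0.109 against 0.367 in replicate 1 for Pgk1, 0.319 against 0.570 for Rvb1 and 0.246 against 0.440 for Rvb2. No biological explanation was tested.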
